A study of Mus musculus with 8 samples.

How the data were processed

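RNA was measured in 8 libraries of mouse bone marrow progenitors (GMLPs, progenitors with granulocyte, monocyte and lymphoid potential) from C57Bl/6 mice aged 8 to 10 weeks. Per the labels' protocols, the cells were kept for 4 days on OP9, a mouse bone marrow stromal line, in medium with IL7, Flt3L, SCF, IL2 and IL15, which permits NK cell growth. CD45-positive, ZsGreen-positive cells were then sorted, between 1000 and 50000 per sample, RNA was purified with a micro-scale column kit, and libraries were made with the SMARTer Ultra Low Input kit. The labels put 2 libraries into each of 4 groups: Hlf-inducible cells without doxycycline, the same kind of cells with doxycycline at 1 µg/ml, wild-type cells infected with a control lentivirus, and wild-type cells infected with a lentivirus carrying the Hlf/Hlf forced dimer. The labels call them duplicate cultures. No replicate pair held identical values over its table, and none was merged.

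The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.8, Bowtie2 2.1.0 and edgeR, without their roles and without an edgeR version. The genome build, the annotation, the counting step and whether strand was used are not given in the sources used here. Each of the 2 comparisons has a deposited table with 4 library columns and the authors' test columns. The library columns deposited by the authors are a normalized signal whose exact definition is not given in the sources used here. The values behave like read counts set to a common library size within the table, and were taken as such, at 20.8 M for the doxycycline table and 23.6 M for the virus table. The values are not whole. Steps of a fixed size, within a tolerance of 0.1 read, could be read in 5 of the 8 libraries and gave effective library sizes between 18.3 and 23.4 M, while the other 3 stayed unresolved. Whole reads could therefore not be recovered, and no count test was run. Per the file headers, the authors' tables also give a log2 fold change of treated over control, a mean log2 CPM, a p-value and a false discovery rate (FDR) per gene. The highest FDR was 0.0500 in the doxycycline table and 0.0490 in the virus table, so each table holds only called genes, and a gene outside it has no value here. From p, rank and FDR, the number of genes the authors tested came to about 20565 and 22292.

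The design had been fixed before the data were examined. It takes the authors' deposited log2 fold changes and FDR below 0.05 as the main result for a table of this kind, in place of a new fit, and no gene set test was made because the genes that did not change are not in the tables. For description, group means, sample SDs (n = 2) and the ratio of means were computed from the library columns. No ratio is given where a group mean was under 3. Where leaving out 1 library moved a ratio over 1.5 times, the library values stand in its place. A limma 3.58.1 fit (R 4.3.3, trend and empirical Bayes) of log2(value + 1) gave standard errors, and its p-values were Benjamini-Hochberg adjusted over the estimated number of genes tested. Fold changes on that scale understate the change of low genes. The limma fit was tested on simulated data with the doxycycline table's 2453 genes, where it called 39% of genes changed 2-fold and 99% of those changed 4-fold with 0 false calls. With the virus table's 458 genes it called 0% at either size, so its adjusted calls carry no information there. The simulated libraries were drawn independently, with 1 common dispersion and no bias along transcript length. The false calls found there do not cover such a bias. P-values of single genes measure the spread between duplicate cultures. The Fisher and permutation tests take genes as units, so their p-values do not measure that spread. Genes read from the same libraries are not independent replicates.

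Gene lists for 23 cell types, states and possible artifacts, 578 distinct genes in all, had been written before the data were examined. Members in each table were counted by direction, and each list was also adjusted over its members alone. A two-sided Fisher's exact test of direction (list members against the other called genes) and a permutation test with 100000 redraws within 10 bins of transcript length were added after seeing the data, with Benjamini-Hochberg adjustment over the lists with at least 3 called members, 20 in the doxycycline and 7 in the virus comparison. Genes named in the text follow a rule of the same date: Hlf, then the 10 highest and 10 lowest fold changes among genes with mean log2 CPM of at least 3 and no overlap of the groups, up to 4 members per list with the smallest FDR, 14 fixed genes whatever they show, and the 10 genes with the smallest larger FDR over both tables. The single results of 4 genes are not reported here, and the counts include them. Names outside this rule are marked as chosen after their values were seen. Ensembl identifiers were looked up in GENCODE mouse release M21 (GRCm38), where 2440 of 2453 and 457 of 458 matched. Coordinates, transcript lengths (the longest annotated transcript) and GC content come from that release, which may not be the authors' build. Symbols are those of the tables, some of them older. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

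Alternatives were FDR below 0.01, a fold change of at least 2, a stricter filter of 5 CPM in 2 libraries, the limma refit, the replicate number as a block and each library left out. Chosen after seeing the data were a pseudocount of 0.1 or 5 in the refit, the length trend removed, crossed pairing, the direction tests, the difference between the systems and its adjustment over the genes that changed the same way. The direction of the shared genes with each library left out was set aside, since groups that do not overlap fix it in advance. The length correction was also tried on the virus table and set aside, since most genes there rose and the trend removed was that common rise. The tables were normalized separately, so levels are compared within a table only.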

Results

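RNA sequencing followed forced expression of Hlf, a transcription factor of the PAR bZIP family, in GMLPs cultured under conditions that permit NK cell growth. Hlf was raised in 2 ways, by doxycycline in Hlf-inducible cells and by a virus carrying a linked Hlf/Hlf dimer in wild-type cells, each against its own control, with 2 libraries per group and 8 in all. Effective library sizes, inferred from the step between values in 5 libraries, lay between 18.3 and 23.4 M. Values below are normalized read counts, mean ± SD of n = 2 duplicate cultures, and every gene said to have risen or fallen passed FDR 0.05 in the authors' deposited table. The spread between duplicates was narrower in the doxycycline table, with a median absolute log2 difference of 0.243 without and 0.198 with doxycycline, than in the virus table, with 0.579 for control and 0.411 for Hlf/Hlf virus.

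The first question was what changed when doxycycline switched Hlf on. No group had doxycycline without the inducible Hlf, so effects of Hlf and of doxycycline itself cannot be told apart in this comparison. Hlf itself (chromosome 11, 90336536 to 90390895, minus strand, GRCm38) rose from 394 ± 27.4 to 10626 ± 735 normalized counts, 27.0-fold, with a limma log2 fold change of 4.75 ± 0.18 (SE). These reads cannot be split into the resident gene and the transgene. Kit (chromosome 5, 75574916 to 75656722, plus strand), the receptor for stem cell factor, rose 7.70-fold, from 1527 ± 173 to 11766 ± 1539. Ly6d (chromosome 15, 74762056 to 74763620, minus strand), which marks early lymphoid cells, fell from 592 ± 11.4 to 11.3 and 1.58 in the doxycycline libraries. Cd7, found on NK, innate lymphoid and T cells, fell from 555 ± 80.3 to 2.68 and 23.6.

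In all, 2453 genes were called, 1405 higher and 1048 lower with doxycycline. Changes were larger among higher than among lower genes. At least 2-fold changes were seen in 815 of the 1405 higher and 191 of the 1048 lower genes. The median log2 fold change was 1.09 among higher and -0.71 among lower genes. In 2448 genes the groups of 2 did not overlap. Direction went with transcript length: the longest annotated transcript had a median of 4828 nucleotides among higher and 1593 among lower genes. Relative to called genes of like length, a limma fit called 353 genes, 131 higher and 222 lower, against 57.3% higher in the main result.

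**Figure D1:**
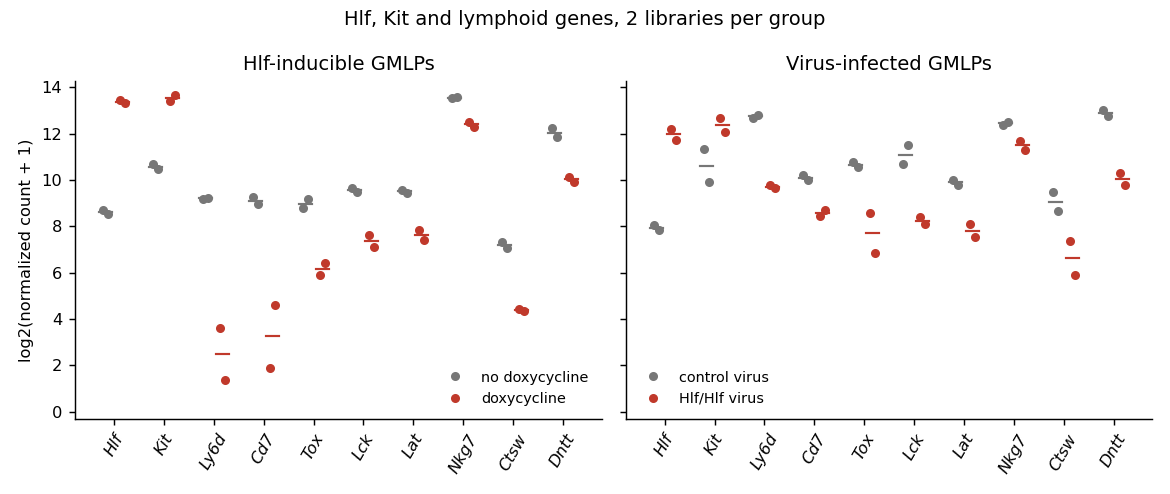
Normalized counts, as log2(count + 1) on the vertical axis, of Hlf, Kit and 8 genes of the lymphoid lists in the doxycycline (left) and virus (right) experiments. A point stands for a library and a line for the mean of the 2 log2 values per group. Of the 8, Nkg7 is also in the primary granule list. Hlf and Kit lie higher and the 8 others lower in both treated groups.

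Among genes with a mean log2 CPM of at least 3, those with the highest fold changes besides Hlf and Kit included Sdc2, a heparan sulfate proteoglycan of the cell surface, which rose from 95.3 and 10.6 to 502 ± 101, and Dock9, a guanine nucleotide exchange factor, which rose 6.77-fold to 415 ± 58.8. Zfp445 rose 6.56-fold to 704 in both libraries, Glce, an enzyme of heparan sulfate synthesis, 6.40-fold to 1021 ± 23.9, and Heatr5b from 163 and 49.4 to 631 ± 12.9. Paqr5 rose 5.94-fold to 1037 ± 258. Vcl, which encodes the adhesion protein vinculin, rose 5.89-fold to 812 ± 55.8, and Btla, an inhibitory immune receptor, 5.79-fold to 747 ± 144. Among the lowest under the same limit, Il1r2, a decoy receptor for interleukin 1, fell 9.86-fold to 35.7 ± 12.3, Cd209a from 436 ± 140 to 26.9 and 69.6, and Phactr2 8.30-fold to 156 ± 13.

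Called members of the NK and innate lymphoid list fell. Of 34 list members 9 were called, all lower, against 42.7% lower among all called genes (Fisher's exact test, adjusted p = 0.00310). Tox, a factor needed for NK and innate lymphoid development, fell 7.07-fold from 509 ± 93.2 to 72.0 ± 18.8, the chemokine gene Ccl5 10.8-fold from 334 ± 83.0 to 30.9 ± 3.83, and Id2, a repressor of E proteins, 4.19-fold from 3134 ± 163 to 748 ± 82.4. Of 22 T lineage members 7 were called, all lower (Fisher's exact test, adjusted p = 0.0128), among them the kinase gene Lck, down 4.59-fold from 756 ± 51.5, the adaptor gene Lat, down 3.64-fold from 724 ± 51.7, Cd5, down 13.1-fold from 187 ± 51.1, and Cd28, down 2.19-fold from 2956 ± 155. Against called genes of like transcript length, neither list's direction passed (permutation test, adjusted p = 0.184 and 0.165).

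In the dendritic cell and MHC class II list 11 of 23 members were called, all lower (Fisher's exact test, adjusted p = 0.00168). Cd74, the invariant chain, fell 7.71-fold from 11200 ± 448 to 1453 ± 60.2, H2-Aa 11-fold from 2438 ± 215 to 222 ± 30.4, and H2-Eb1 8.40-fold from 1107 ± 48.8 to 132 ± 16.7. This list shares Id2 with the NK and innate lymphoid list and Ly6d with the lymphoid priming list. Called members of both neutrophil lists fell as well. Of the 17 primary granule members 9 were lower and 0 higher (Fisher's exact test, adjusted p = 0.00310). Elane, neutrophil elastase, fell 2.71-fold from 15768 ± 1573 to 5826 ± 294, Ms4a3 3.12-fold to 1308 ± 138, and Hp 2.66-fold to 463 ± 65.9. Of 23 late neutrophil members 6 were lower and 0 higher (Fisher's exact test, adjusted p = 0.0241), with Ngp down 3.66-fold to 459 ± 104, S100a8 down 3.68-fold to 221 ± 55.8 and Camp down 5.14-fold to 43.1 ± 15.5. By transcript length alone, 8.57 of the 9 primary granule genes and 5.87 of the 6 late neutrophil genes would be lower, and 9.50 of the 11 in the dendritic cell list (permutation tests within length, adjusted p = 1, 1 and 0.451).

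The lists of other lineages were mixed, and their direction did not pass the added test. Of 40 monocyte and macrophage members 7 rose and 5 fell. Cd14 rose 4.60-fold to 1194 ± 127, the chemokine receptor gene Ccr2 2.42-fold to 12378 ± 1419 and Csf1r, the receptor for M-CSF, 2.34-fold to 3784 ± 608, while Lgals3 fell 2.42-fold to 630 ± 42.5. In the mast cell, basophil and eosinophil list 3 rose and 6 fell: Mcpt8, a basophil protease, fell 4.42-fold to 1124 ± 67.7 and Prg2 from 548 ± 31.1 to 109.9 and 221. The megakaryocyte and erythroid list had 1 higher member, Car1, listed at 0 in both untreated libraries and at 72.9 and 22.2 with doxycycline, and 5 lower, with Gfi1b down 1.95-fold and Car2 down 1.76-fold. In the stem cell and multipotent progenitor list 5 rose and 1, Gfi1b, fell: beside Kit, Angpt1 rose 2.27-fold to 3807 ± 297 and Cd34 1.72-fold from 19488 ± 1632 to 33574 ± 1703.

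B lineage genes went both ways, with 4 of 21 higher and 3 lower. Igll1, part of the surrogate light chain, rose from 3.29 ± 2.90 to 73.2 ± 41.6, at a low level. Arpp21 fell 3.40-fold to 80.0 ± 33.3 and Cd72 1.73-fold to 752 ± 150. In the lymphoid priming list 3 rose and 4 fell. Dntt, the terminal transferase of early lymphocytes, fell 4.05-fold from 4213 ± 786 to 1042 ± 98.7, while Ikzf1 rose 1.5-fold. Relative to called genes of like length the sign for Ikzf1 turned, at -0.49 ± 0.10 on the limma log2 scale, without passing (limma adjusted p = 0.0627).

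Cell cycle genes split as well, with 6 higher and 4 lower in the S phase list and 5 higher and 7 lower in the G2 and M phase list. Mcm4 rose 1.64-fold and Bub1b 2.19-fold, whereas Gins1 fell 1.69-fold and Ube2c 2.43-fold. Cdkn1a, which encodes the inhibitor p21, fell 3.06-fold from 1140 ± 68.9 to 373 ± 19.4, and Rbl2 rose 3.14-fold to 768 ± 132, among 2 lower and 2 higher cell cycle inhibitors. Of the cytokine receptors 7 rose and 1 fell, with Il6st up 3.06-fold and Tgfbr1 2.96-fold. In the interferon list 6 rose and 1, Bst2, fell 1.77-fold. Lineage transcription factors had 3 higher and 3 lower members, the PAR bZIP and circadian list 2 higher (Per3 1.94-fold and Cry2 2.69-fold) and 1 lower, and apoptosis regulators 1 each way (Casp9 higher, Bax lower). In the amino acid response list, kept as a check on doxycycline itself, Cebpg rose 2.00-fold, Aars 1.66-fold and Pycr1 fell 1.91-fold. The stromal list had 4 higher members, among them Thbs1 at 3.91-fold, and 1 lower, Sparc, down 5.50-fold. Hspe1 of the stress list and mt-Co1 of the mitochondrial genome were 1.49-fold and 1.78-fold lower. Adjusted over the list alone, 22 of the 23 lists kept the same count, and the stress list went from 1 to 0. Members without a value were taken as unchanged and the highest deposited p-value was 0.00597. A count could therefore not rise and had little room to fall. Of the fixed genes, Ebf1, Il7r, Rag1, Eomes, Nfil3, Gata3, Irf8, Cebpa, Mpo and Lmo2 have no value in the table used here.

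**Figure D2:**
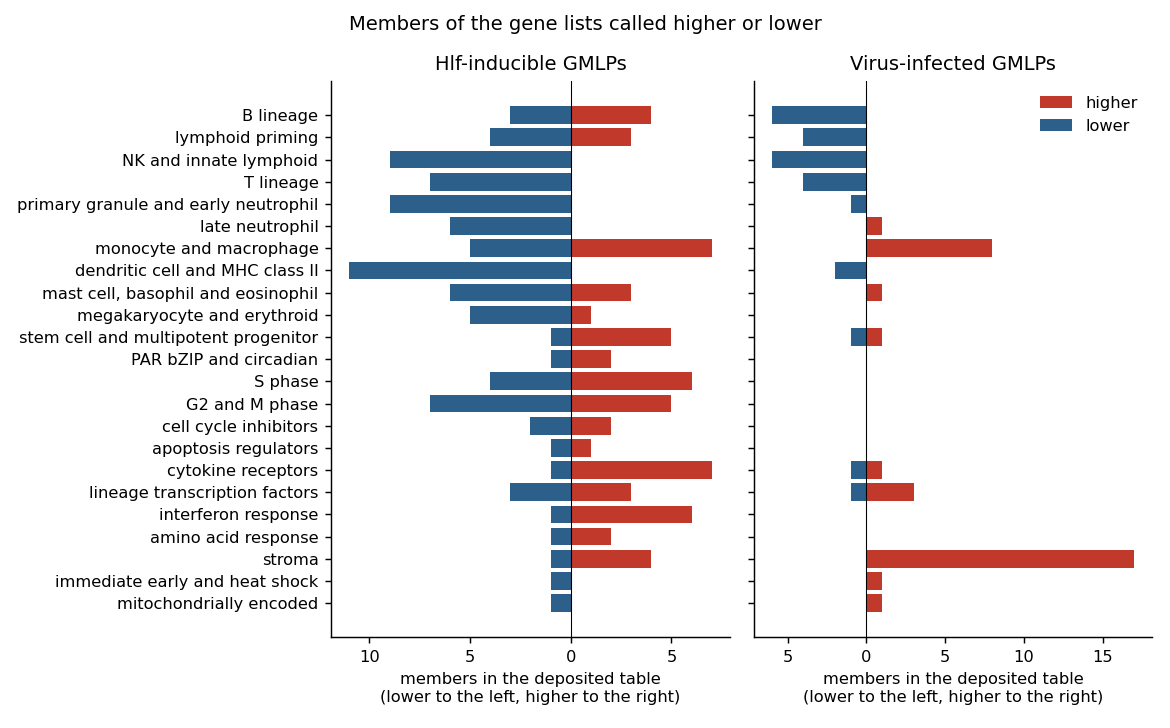
Members of each of the 23 gene lists found in the deposited tables, as a count of genes on the horizontal axis, with higher members to the right and lower members to the left, for the doxycycline (left panel) and virus (right panel) comparisons. With doxycycline all 9 NK and 7 T lineage members were lower, and with the virus 17 stromal members were higher.

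**Figure D3:**
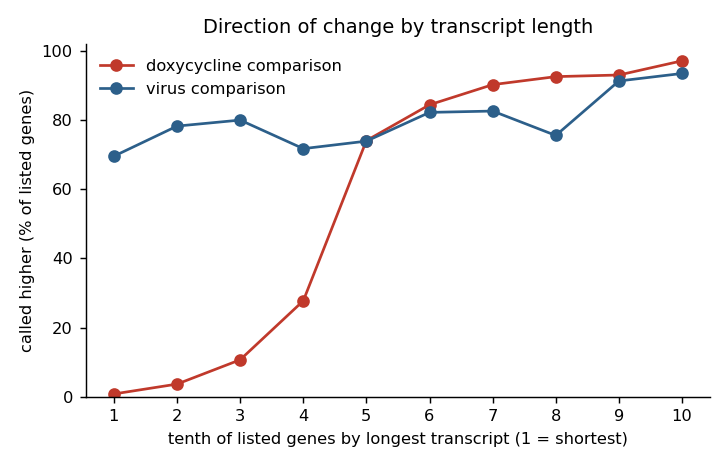
Share of called genes that were higher, as a percentage on the vertical axis, in 10 equal bins of genes by longest annotated transcript on the horizontal axis, for both comparisons. With doxycycline the share ran from 0.820% in the shortest to 97.1% in the longest bin, and with the virus from 69.6% to 93.5%.

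The calls were the authors' edgeR results on 2 libraries per group. A limma fit of the deposited values with the replicate number as a block, which the labels do not tie to a shared culture, called 1318 of the 2453 genes, 1014 higher and 304 lower (76.9% higher against 57.3%).

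The second question was what changed with the Hlf/Hlf virus. Hlf rose 16.5-fold, from 246 ± 23.2 to 4067 ± 963, with a limma log2 fold change of 4.02 ± 0.28 (SE). Kit rose from 2543 and 975 in the control libraries to 6421 and 4312 in the Hlf/Hlf libraries. Lymphoid genes fell: Igj, the immunoglobulin J chain (named Jchain now), fell 27.2-fold from 3285 ± 453 to 121 ± 18.5, Ly6d 8.14-fold from 6833 ± 408 to 839 ± 48.9, and Dntt 7.09-fold from 7634 ± 885 to 1076 ± 278. Rag1, part of the recombinase that assembles antigen receptor genes, was listed at 476 and 172 in the control libraries and at 0 in both Hlf/Hlf libraries. Matrix genes of stromal cells rose, such as Fn1, fibronectin, from 186 and 733 to 17108 ± 499.

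In this comparison 458 genes were called, 366 higher and 92 lower, and 362 and 90 of them by at least 2-fold. In all 458 the groups of 2 did not overlap. The called genes made up 1.59% and 1.67% of the common library size in the control libraries and 3.45% and 3.22% in the Hlf/Hlf libraries.

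Of the B lineage members 6 of 21 were called, all lower, against 20.1% lower among all called genes (Fisher's exact test, adjusted p = 0.000201). Bfsp2 fell 8.49-fold to 63.5 ± 26.9 and Arpp21 from 1940 ± 452 to 680 and 274, and Ms4a1 and Fcrla were listed at 0 in both Hlf/Hlf libraries, from 72.5 ± 6.12 and 63.0 ± 34.7. The lymphoid priming list had 4 lower and 0 higher members (Fisher's exact test, adjusted p = 0.00270), with Ccr9, a chemokine receptor of thymus-seeding cells, down to 146 and 326 from 1170 in both controls. All 6 called NK and innate lymphoid members were lower (Fisher's exact test, adjusted p = 0.000201): Tox fell from 1623 ± 166 to 375 and 115, Cd7 2.86-fold to 382 ± 54.0, and Il2rb, the receptor subunit shared by interleukins 2 and 15, from 206 ± 2.70 to 20.5 and 2.61. All 4 called T lineage members were lower (Fisher's exact test, adjusted p = 0.00270): Cd6 fell from 422 ± 134 to 42.2 and 0, Thy1 9.53-fold to 38.8 ± 6.79, Lck 7.52-fold to 303 ± 47.1 and Lat 4.17-fold to 228 ± 59.6. These 4 lists kept their direction against called genes of like length (permutation test, adjusted p between 0.000735 and 0.00355). Spib, a factor of plasmacytoid dendritic and B cells, fell 12.4-fold to 18.8 ± 5.74, and with Ly6d made up the 2 called members of the dendritic cell list. Outside the lists, Tcrg-C1, a T cell receptor gamma constant gene whose reads its near copies can share, fell from 666 ± 30 to 23.0 and 48.3, Lax1 from 943 ± 81.4 to 121 and 6.11, and Tmem108 9.33-fold to 105 ± 47.0.

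The stromal list, written to follow RNA of the OP9 layer, had 17 of 34 members called, all higher (Fisher's exact test, adjusted p = 0.0424, and 0.0701 in the permutation test within length). Col1a2, a chain of collagen I, rose 45.9-fold from 158 ± 21.5 to 7242 ± 482, Col6a1 27.9-fold to 7248 ± 138, and Lox, which crosslinks collagen, 44.1-fold to 1710 ± 115. In 15 of the 17 the second control library also lay above the first, and the median log2 ratio over the 17 was 1.85. Among genes with a mean log2 CPM of at least 3, the highest fold changes were those of Dnm3os and Plcd1, both listed at 0 in the controls and at 521 ± 205 and 426 ± 55.6 with the Hlf/Hlf virus, and Olfml2b, F3 and Mxra8, whose control means were under 3 and which reached 729 ± 212, 520 ± 82.3 and 587 ± 75.5. Dnm3os lies antisense within Dnm3, and without strand its reads cannot be told from those of its partner. Fbln2, a matrix protein, rose from 0.00447 and 7.12 to 1073 ± 109, Capn6 198-fold from 4.46 ± 0.581 to 883 ± 216, Nqo1 from 2.03 and 7.20 to 400 ± 124, Kitl, the ligand of Kit, from 8.82 ± 0.393 to 1103 and 354, and Nfib from 3.04 and 14.4 to 619 ± 167.

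**Figure D4:**
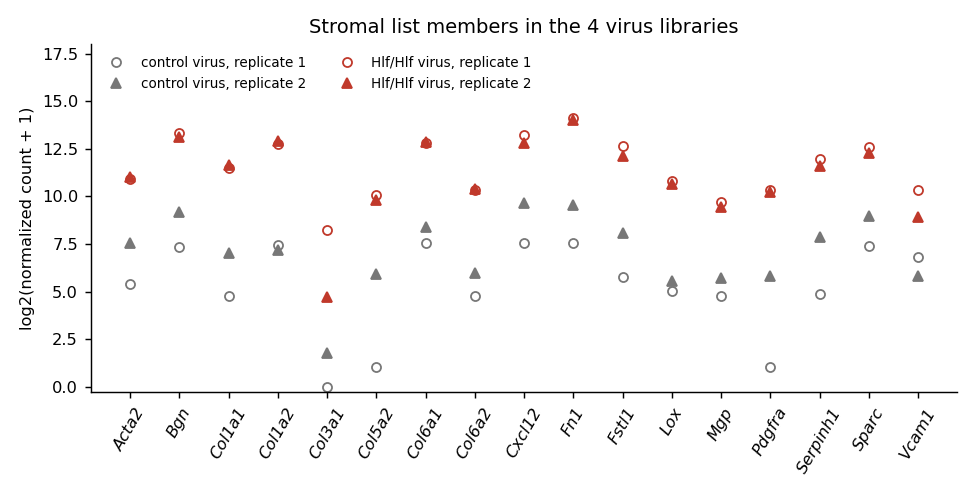
Normalized counts, as log2(count + 1) on the vertical axis, of the 17 called stromal list members in the 4 virus libraries, circles for replicate 1 and triangles for replicate 2. Both Hlf/Hlf libraries lie above both control libraries for each gene, and in 15 of 17 control replicate 2 lies above control replicate 1.

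All 8 called monocyte and macrophage members of 40 were higher, which the added test did not set apart from the other called genes (Fisher's exact test, adjusted p = 0.429). Maf rose 26.7-fold to 517 ± 1.56, Gpnmb from 2.03 and 18 to 344 and 966, Lgals3 3.51-fold to 2126 ± 193 and Ccl9 2.71-fold to 5638 ± 160. Of 4 lineage transcription factors, Maf, Id3 (4.48-fold) and Snai2 (from 5.06 and 91.0 to 828 ± 300) rose and Mycn fell 6.64-fold to 108 ± 14.3. Mycn and Kit were the 2 called stem cell list members, Kit and Il2rb the 2 cytokine receptors, and Kit the 1 member of the mast cell list. Nkg7 fell 1.92-fold as the 1 primary granule member, and Anxa1, of the late neutrophil list, rose 5.50-fold. Fos rose 2.08-fold and mt-Co1 1.99-fold, each alone of its list. In 8 of the 23 lists 0 members were called: S phase, G2 and M phase, cell cycle inhibitors, interferon, amino acid response, apoptosis, PAR bZIP and circadian, and megakaryocyte and erythroid genes. Adjusted over the list alone, all 23 lists kept the same count, which the highest p-value in the authors' deposited table, 0.00101, fixes for lists of up to 49 genes. Of the fixed genes, Ebf1, Il7r, Eomes, Nfil3, Id2, Gata3, Irf8, Cebpa, Csf1r, Mpo, Elane and Lmo2 have no value in the table used here. A limma fit called 0 of the 458 genes after adjustment and 454 at an unadjusted p under 0.05, and the authors' edgeR called 458.

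The design repeats the question in 2 systems with separate controls, so the called genes were set side by side. Hlf and Kit rose in both. Socs2, a suppressor of cytokine signalling, fell from 369 ± 43.9 to 34.4 and 77.3 with doxycycline and 6.91-fold from 5675 ± 352 with the virus. Ly6d, Dntt and Lck fell in both as given above. Il1r2 fell 9.86-fold and 5.96-fold, Sla2, an adaptor of lymphocyte receptors, 7.99-fold and 6.24-fold, and Myl10 4.40-fold and 5.14-fold. Igj, 172 ± 11.1 without doxycycline, was at 0 and 1.22 with it. Among the 10 genes with the smallest larger FDR, Anxa2 alone moved apart: it fell 2.06-fold from 8089 ± 779 with doxycycline and rose 4.52-fold from 2570 ± 645 with the virus.

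In total 104 genes were called in both systems. Of these 44 were higher in both and 42 lower in both, 16 were lower with doxycycline and higher with the virus, and 2, Hcn3 among them, the reverse. Independent lists over 20565 genes would share 25, 4.69, 18.7 and 6.29 genes in that order. These are descriptions, because the genes tested in both are not known and no enrichment test was made. The genes lower in both were 45.7% of all genes lower with the virus, and those higher in both 12% of all genes higher with it. Within the 104, direction in 1 system went with direction in the other (Fisher's exact test, two-sided, p = 2.04e-13, across genes, which are not independent replicates). Across these genes the authors' deposited tables gave log2 fold changes with a Pearson r of 0.375 and a Spearman rho of 0.548, and across the 73 with a mean log2 CPM of at least 3 in both a Pearson r of 0.801. Of the members of the 4 lymphoid lists, 10 were lower in both (Arpp21, Cd6, Cd7, Ctsw, Dntt, Lat, Lck, Ly6d, Nkg7 and Tox), 0 higher in both and 1 moved apart. Hcn3 and Ctsw were chosen after their values were seen.

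**Figure D5:**
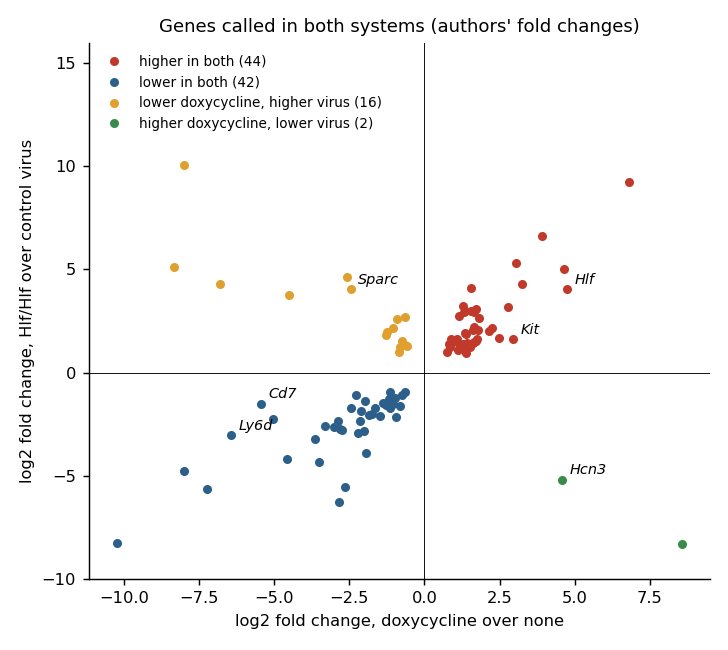
Log2 fold changes from the authors' deposited tables of the 104 genes called in both, doxycycline over none on the horizontal and Hlf/Hlf over control virus on the vertical axis, with a point per gene coloured by direction. In all, 86 genes lie in the lower left or upper right, with Hlf and Kit at the upper right and Ly6d and Cd7 at the lower left.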

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

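All tests in this part were chosen only after the results were seen, as were the genes named here and not in the report. A limma contrast of the virus effect minus the doxycycline effect, over the 104 genes called in both tables, found a difference in 26 genes (adjusted p under 0.05), and these were marked for that difference. The tables were normalized separately and their cells differ, so the contrast compares 2 fold changes and not 2 levels. It pools the spread of both systems in 1 fit over genes picked as called in both. Duplicates differed more in the virus table, by a median absolute log2 difference of 0.579 and 0.411 against 0.243 and 0.198. Adjusted p-values near 0.05 are therefore weak evidence. The values below are the virus effect minus the doxycycline effect on the log2(value + 1) scale.

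For the 18 genes called in opposite directions a difference follows from how they were picked. Their values describe its size on this scale only and are no further evidence for it. Of these, 16 were lower with doxycycline and higher with the virus. Secreted and matrix genes gave Olfml2b 13.18, Sod3 9.82, Efemp1 8.44, Sparcl1 7.91, Efemp2 7.60, Sparc 6.68 and Spp1 3.57. The largest of these depend on the 1 added to each value, because the genes are low in some groups. With doxycycline Olfml2b, Sod3 and Efemp1 gave -4.22, -3.76 and -3.34 on this scale. The authors' deposited table gives -8.00, -6.80 and -8.35. The others were S100a6 at 3.36, Ctsh at 3.36, Anxa2 at 3.24, Lgals3 at 3.10, Cd63 at 2.27, Mrps6 at 2.02, Ms4a6c at 1.99, Lgals1 at 1.87 and mt-Co1 at 1.81. Of the 2 genes that moved the other way, Hcn3 gave -8.96, with at most 90.0 normalized counts in any library. Of the 86 genes that changed the same way in both, adjusted alone, 4 differed by limma (adjusted p between 0.0344 and 0.0390): Lpl at 1.93 rose further with the virus, and Cd7 at 4.34, Ly6d at 3.69 and Lsp1 at 1.2 fell less. Aplp2 at 1.58, Maged1 at 1.57, Nav1 at 1.56 and Ifitm1 at -1.19 did not pass that adjustment (limma adjusted p between 0.0592 and 0.108), and passed over all 104 genes only beside those called in opposite directions.

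Genes of stromal cells rose with the Hlf/Hlf virus, 17 of the list's 34 members and 0 fell, by a median log2 fold change of 4.90 in the authors' deposited table. Library size does not account for this, as the largest ratio between the 3 resolved virus libraries was 1.2. A candidate explanation is RNA from the OP9 layer: the same genes differed between the 2 control libraries by a median log2 ratio of 1.85, where genes that fell differed by 0.08, though the sort for CD45 and ZsGreen would remove OP9 cells and the most abundant members, Fn1, Bgn and Cxcl12, reached 17108, 9733 and 8395 normalized counts. The shift between controls was not limited to the list, since 94 other genes that rose over 8-fold differed by a median log2 ratio of 1.21, and some list genes are also expressed by blood cells. Expression induced by Hlf in the infected cells cannot be told apart from this, because with doxycycline 1 of the 17 (Col5a2) was higher and 1 (Sparc) lower, and the others have no value there.

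Longer transcripts were higher and shorter ones lower with doxycycline, with a rank correlation of 0.66 between fold change and transcript length across 2440 genes, against at most 0.050 in 100 shuffles. GC content is argued against as the cause, because the correlation was 0.64 with GC held constant. A length bias that differs between libraries may contribute, since duplicates of the same group also differed along length. Across the 2235 genes with a mean log2 CPM of at least 3, the rank correlations were 0.51 without and -0.50 with doxycycline (smaller size 0.503). Within the genes that fell these correlations were 0.31 and -0.23, and within the genes that rose -0.03 and -0.13. In size the duplicates differed less than the treatments. The median log2 ratio of replicate 1 over replicate 2 was 0.247 for higher and -0.161 for lower genes without doxycycline. With doxycycline it was -0.074 and 0.210. Between treatments the median log2 fold changes of all called genes were 1.09 and -0.71. An effect of Hlf or of doxycycline itself on long genes stays open, since each group has 1 treatment and the virus comparison gave a rank correlation of 0.13.

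Members of the lymphoid lists fell in both systems, 10 genes with a median log2 fold change of -2.51 with doxycycline and -2.54 with the virus in the authors' deposited tables. Transcript length does not account for the size of their fall, because relative to called genes of like length their median doxycycline fold change was still -2.54 (quartiles -4.35 and -1.60), with 10 of 10 below 0 and 9 called by limma. These 10 were picked for falling in the same libraries, so their sign and calls are no independent evidence. The direction of the 4 whole lists with doxycycline did not pass within length (permutation test, adjusted p between 0.165 and 0.451). Dilution of the sorted cells by stromal RNA would lower these genes by 1 common factor in the virus system. Their log2 falls had an SD of 1.34, against 0.847 from the duplicates (F test across the 10 genes, unadjusted p = 0.0471). For the 6 with a mean log2 CPM of at least 5 these were 0.805 and 0.389 (F test, unadjusted p = 0.0241). The values argue, weakly, against dilution as the sole cause for these genes. A part played by dilution stays open. All 8 called monocyte list members were higher, but so were 79.9% of all called genes, and the other 32 members have no value there. Fewer lymphoid cells and less lymphoid RNA per cell cannot be told apart in bulk RNA. The quartiles of the virus log2 fold changes lay 0.86 apart.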

How the results depend on the processing

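The length, crossed pairing, pseudocount and direction tests were chosen after seeing the data. The cause of each shift was not tested, except that stricter thresholds keep fewer genes and left-out fits have fewer libraries.

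With doxycycline, FDR below 0.01 kept 1490 of 2453 genes, a fold of at least 2 kept 1006, the replicate block gave 1318 (1014 higher, 304 lower) and the length correction 353, while 4 other settings gave between 1966 and 2322. With the virus, FDR below 0.01 kept 305 of 458 genes, limma called 0 with a pseudocount of 1 or 5, 59 with 0.1 (55 of them listed at 0 throughout 1 group) and 84 with the replicate block (71 such genes). Crossed pairing gave 2450 and 0 genes. Deviations of like-numbered libraries correlated at -0.16 (rank -0.37) and -0.07 (rank -0.11), which gives no sign of pairing by number but rests on 2 pairs. With doxycycline the correlation was -0.28 across 2245 genes with a mean log2 CPM of at least 3. Unlike-numbered libraries thus deviated together there, and crossed pairing called more than the 2199 genes of the fit without a block. The labels do not explain this. The virus labels number the cultures 1 and 3 against 2 and 3, so whether culture 3 was shared stays open beside the block result. Leaving out each library gave 41 to 60 genes with doxycycline and 18 to 63 with the virus, and 4 to 11 and 0 to 5 list members, where the lone library is assumed to vary like the others. These fits say nothing about stability: without a control virus library all 18 calls were lower, without an Hlf/Hlf library all 63 were higher, and each of these genes was listed at 0 in both remaining duplicates. With doxycycline 30 to 36 of the calls were listed at 0 throughout 1 group. FDR below 0.01 in both kept 51 of the 104 shared genes, 43 of them moving the same way. Lists with a lopsided direction went from 5 to 0 within length with doxycycline and from 5 to 4 with the virus.

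Relative to called genes of like length, 43 of 91 named genes were called in the same direction, 38 kept their direction but not the call and 10 turned without passing in the new direction, among them Ikzf1 -0.49, Per3 -0.19, Pola1 -0.30 and Aars -0.39 from higher, and Cd9 0.066, Gins1 0.024, Bax 0.14, Bst2 0.067 and Hspe1 0.24 from lower. With the replicate block 14 of 91 lost the call. No named gene turned under the other settings. Groups that do not overlap, as in 2448 of 2453 and all 458 called genes, fix this in advance, so it is no evidence of stability.

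Not run: count-based settings (DESeq2, size factors, unscaled totals, exact test), FDR below 0.1, no filter, and the set tests, since the tables hold no counts and only called genes.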

Other observations

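The genes below were noticed after seeing the data and are described without a test. The first 2 groups were not among the lists. With doxycycline 75 genes of ribosomal proteins were called and all 75 were lower, by a median log2 fold change of -0.70 in the authors' deposited table, with a range from -0.87 to -0.47. Their transcripts are short, with a median longest transcript of 1106 nucleotides, and they moved like called genes of that length, since of those with 1005 to 1499 nucleotides 96.3% were lower, with a median log2 fold change of -0.67. Another 60 called genes were picked by the name stems of respiratory chain and ATP synthase subunits, which also catch assembly factors such as Cox14. Of these 58 were lower and 2 higher, with a median log2 fold change of -0.66 in the authors' deposited table. Their median longest transcript was 913 nucleotides. Of called genes with up to 1002 nucleotides 99.2% were lower, with a median of -0.74. With the virus, 1 ribosomal protein gene was called, and it was higher.

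Il15, the gene of a cytokine that was also in the medium, rose in both systems, from 83.6 and 207 to 641 ± 28.3 with doxycycline and 4.10-fold from 156 ± 24.8 to 641 ± 116 with the virus (mean ± SD of normalized counts, n = 2). Igha, an immunoglobulin heavy chain constant gene whose reads related genes can share, was listed at 82.8 and 211 without doxycycline and at 0 in both libraries with it, and at 33.4 and 42.6 with the control virus and 0 in both Hlf/Hlf libraries. Mecom and Fgd5 were the called members of the stem cell list not named elsewhere. Mecom, a regulator of stem cells, rose 5.38-fold with doxycycline from 27.9 ± 5.50 to 150 ± 20.0, and Fgd5, which marks stem cells, was listed at 0 in both untreated libraries and at 17.7 and 19.1 with doxycycline. All 4 were chosen after their values were seen.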
